A study of Homo sapiens with 10 samples.

How the data were processed

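HAP1 is a near-haploid human line derived from the chronic myelogenous leukaemia line KBM-7, and the labels say that the cells were kept mostly as diploid cells. SMUG1 is a uracil-DNA glycosylase, an enzyme that removes uracil and some oxidised pyrimidines from DNA. Total RNA from parental (WT) and SMUG1-edited (KO) cells at passage 14 was sequenced in 3 libraries per genotype, made with the Lexogen SENSE Total RNA-Seq kit per the labels' protocols. A second assay, 3' rapid amplification of cDNA ends (3' RACE) of the telomerase RNA TERC, was sequenced at passage 8 in 2 clones per genotype, with Illumina TruSeq Nano libraries per the labels. Groups and replicate numbers were taken from the sample titles. The column names of the RNA-seq libraries carry the name of 1 clone per genotype, in WT as in KO, and no label says that the libraries came from separate cultures, so their p-values measure the spread between these libraries, which may be technical.

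The deposited RNA-seq table holds raw read counts for 60675 Ensembl genes and 6 libraries. Per the submitters' processing notes, STAR, HTSeq and limma were used on genome build GRCh38.p7; versions, filters and the strand setting are not given in the sources used here. The deposited RACE table holds a signal, the read depth at each position of the TERC transcript in RPM, per the file headers. Bowtie2, bedtools and cutadapt are named for it in the submitters' processing notes. What the RPM scale is relative to is not stated. Both WT clones pass 1000000 RPM, more than a share of a library's own reads can reach, so levels between clones rest on an unknown total. The number of reads behind a position is not given, so no counting interval was attached to it. No column of per-sample values was left unused.

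Gene positions and types came from GENCODE release 29 on GRCh38, which held 57055 of the 60675 gene identifiers. Current symbols were found for 41209. The patch level of that annotation and the authors' gene set can differ, and coordinates are those of GENCODE, 1-based. The mature end of TERC was taken from RefSeq on the same chromosome coordinates.

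Library totals ran from 39376228 to 45490786 counts. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (17609, holding all but 0.0665% of the counts), scaled by TMM, and tested with the robust quasi-likelihood F test, KO minus WT, two-sided. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called changed. CPM, counts scaled to a common library total, were computed from the TMM-scaled totals, and group values are means ± SD over 3 libraries. Gene lists (27, of which 26 had at least 5 tested members) and chromosomes were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other tested genes, and fry asks whether the list itself moves to one side. The lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes SMUG1, TERC, 5 telomerase proteins and 5 RNA or DNA processing enzymes whatever their p; the 12 largest rises and 12 largest falls among changed genes with an official symbol, a mean of at least 1 CPM and no overlap between groups; and up to 4 members per list with the smallest p among changed genes. A fold against a group without counts was computed against a floor of 3 counts over the group, and a ratio against 1 to 3 counts has an exact 95% Poisson interval.

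Spread between replicates exceeded counting error at every level. Among genes with 3 to 10 counts on average, the variance between replicates was 11.4 times the mean in WT and 10.9 times the mean in KO, and at 1000 to 3000 counts it was 16.5 and 15.1 times the mean, where counting error alone gives 1. The reads carry no molecular identifiers in the sources used here, and whether duplicate reads were removed is not stated. Floors and intervals allow for counting error alone, so they are too narrow for counts with this spread, whatever its source. No pair of replicates agreed within sampling noise, with chi-square values per gene between 14.3 and 20.4.

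How the counts treat overlapping genes was checked against GENCODE. Of 247 single-exon genes that lie inside an exon of another gene on the same strand with at least 1000 counts, 9 (3.64%) had any count. On the opposite strand it was 61 of 169 (36.1%), and 4762 of 19748 (24.1%) where no exon overlapped. Reads over 2 genes on the same strand were thus seldom credited to the inner gene. Whether the outer gene kept them was not tested.

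RACE depth was expanded to single positions, and the share of the summed depth that lay past the mature 3' end was computed per clone. KO and WT were compared with an exact two-sided permutation test, for which 2 clones against 2 allow no p below 0.333. Alternatives were DESeq2 1.42.0 size factors in the edgeR fit, library totals alone, no filter or a filter of 1 CPM in 3 libraries, limma-voom, the DESeq2 Wald test, the replicate number as a block, and each library left out in turn. For RACE they were another denominator, a moved boundary, the maximum in place of the sum, and each clone left out. The closing section gives their effect. The edgeR steps were tested on simulated data for the comparison of KO with WT, drawn from the real means and totals and the edgeR dispersions. In a single draw, 200 genes were changed 1.5-fold, 2-fold or 4-fold, and a list of 25 more was raised 1.5-fold. With 17348 genes tested, 41.5% of the 1.5-fold, 54.0% of the 2-fold and 76.6% of the 4-fold changes were recovered. These are shares of the 65, 63 and 64 genes among the 200 that passed the filter. Recovery meant a call in the right direction. Of 119 calls, 2 were false, on genes left unchanged. Position-wise values and figures were made with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.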

Results

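RNA-seq compared 3 libraries labelled WT with 3 labelled KO, and 3' RACE of TERC compared 2 WT clones with 2 KO clones. Total counts were 45490786, 39376228 and 41071449 in WT replicates 1 to 3, and 44553493, 42554605 and 41975151 in KO replicates 1 to 3. Counts from mitochondrial genes made up 9.70%, 9.73% and 10.5% of the WT and 11.2%, 10.9% and 10.9% of the KO libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow).

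The series asks whether loss of SMUG1 changes the telomerase RNA and its end. The count of the edited gene was not lower in the KO libraries. SMUG1 (ENSG00000123415, chromosome 12, 54121277 to 54189008, minus strand, GRCh38) had 1179, 907 and 930 counts in WT replicates 1 to 3, and 1389, 1021 and 1245 in KO replicates 1 to 3. This was 23.9 ± 1.83 CPM in WT and 28.2 ± 3.71 CPM in KO (SD, n = 3), a log2 fold change of 0.24 (SE 0.13; edgeR quasi-likelihood adjusted p = 0.269). A count summed over the whole gene does not read the edited bases, so it gives no check of the labels, and KO stands below for the libraries labelled KO.

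The count of TERC, the RNA that carries the telomere repeat template of telomerase, was lower in every library labelled KO than in every WT library. TERC had 2172, 1770 and 1614 counts in WT replicates 1 to 3 and 408, 394 and 464 in KO replicates 1 to 3. The mean was 44.1 ± 4.25 CPM in WT and 9.80 ± 0.965 CPM in KO (SD, n = 3), a log2 fold change of −2.17 (SE 0.13; edgeR adjusted p = 1.22e-11), or 4.50-fold. TERC (ENSG00000270141) is annotated as a non-coding RNA of a single exon on chromosome 3, 169764520 to 169765060, minus strand. A second entry of the table, RF00024 (ENSG00000277925), covers 169764610 to 169765047 on the same strand, and has 0 counts in all 6 libraries. RF00024 leaves free 13 bases at the 5' end of TERC and 90 bases past the mature 3' end. With 0 counts in RF00024, reads over both entries were not credited to RF00024. Whether they were credited to TERC or to neither is not known, so the part of the locus that the TERC count covers is open. If they were credited to neither, the TERC count holds only reads that reach those 13 or 90 free bases. It would then not measure the rest of the RNA.

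The mRNAs of the telomerase proteins did not follow the TERC count. TERT, the reverse transcriptase, was at 37.7 ± 1.71 CPM in WT and 41.5 ± 8.58 CPM in KO (SD, n = 3; edgeR adjusted p = 0.555). The mRNAs of proteins that bind TERC had log2 fold changes of 0.04 for DKC1, 0.00 for NOP10, 0.12 for NHP2 and 1.31 for GAR1 (adjusted p between 0.171 and 0.992), with GAR1 below 1 CPM in both groups. TERC was the only changed gene of 14 tested in the telomerase list, and the list as a whole was not past the threshold (camera adjusted p = 0.782, fry adjusted p = 0.259). Of the enzymes that trim or tail the TERC 3' end, PARN (0.14), TENT4B (−0.06) and TOE1 (−0.01) were not past the threshold, with adjusted p of 0.54, 0.876 and 0.982. Of 16 genes in the list of TERC 3' end processing, ZCCHC8, the scaffold of the nuclear exosome targeting complex, was the only changed gene. It rose from 97.9 ± 2.94 to 146 ± 1.71 CPM (log2 fold change 0.57, SE 0.06, edgeR adjusted p = 5.32e-07). Against all other genes this list was not past the threshold (camera adjusted p = 0.782), while fry, which looks at the list alone, called it higher (adjusted p = 0.0439).

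**Figure D1:**
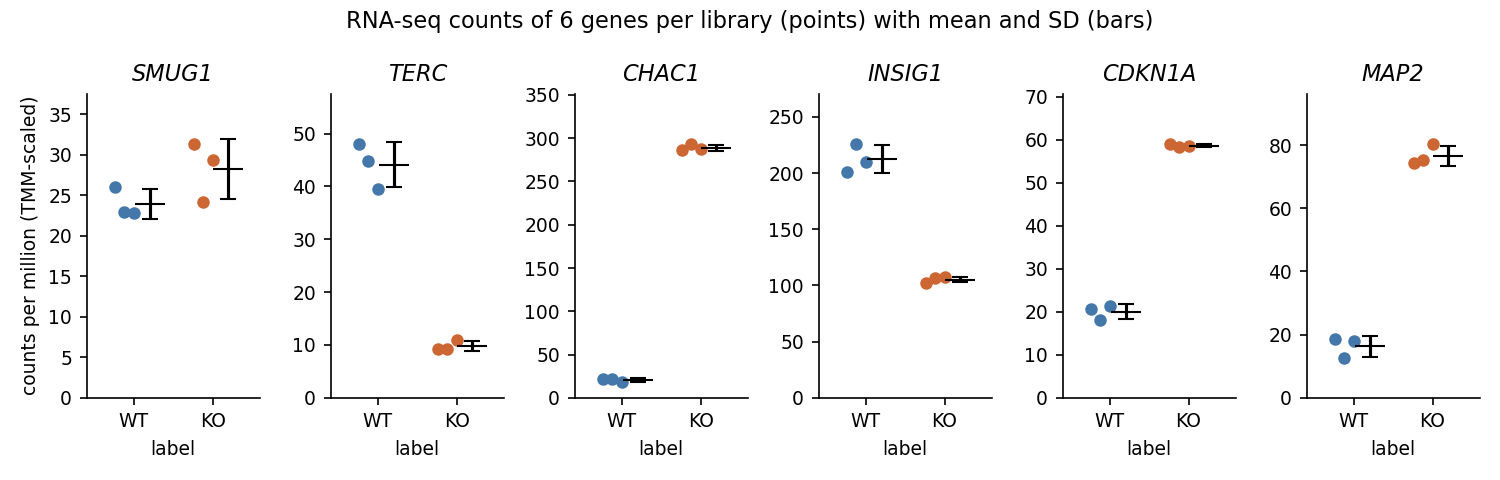
TMM-scaled CPM (vertical axes, each from 0) of 6 genes in the RNA-seq libraries labelled WT and KO; points are single libraries, and the bar beside them is the mean with its SD (n = 3). SMUG1 overlaps between labels, TERC lies at 44.1 CPM in WT and 9.80 CPM in KO on average, and CHAC1 lies at 20.7 and 289 CPM.

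In the RACE libraries, TERC ended within a few bases of the mature 3' end in both genotypes. Depth was highest at position 381 to 384 of the transcript, and it peaked at 1077106 and 1025977 RPM in WT clones 1 and 2 and at 504532 and 406294 RPM in KO clones 1 and 2. The ratio of the WT to the KO mean was 2.31 (exact two-sided permutation p = 0.333, the smallest that 2 against 2 allow). The WT peaks pass 1000000 RPM, more than a share of a library's own reads can reach, so the unit is unknown and the ratio is no measure of the amount of TERC. The largest fall in depth came right after the mature end, at chromosome 3 position 169764610, where 54.7% and 54.9% of the peak depth was lost in the WT clones and 54.2% and 59.1% in the KO clones. The RNA ends there with AGGACTCGGCTCACACATGC, and the genome goes on with AGTTCGCTTT.

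Depth past the mature end was a small share of the summed depth, and slightly larger in the KO clones. Of all depth, 0.388% and 0.412% lay past the mature end in WT clones 1 and 2, and 0.455% and 0.483% in KO clones 1 and 2. The sum runs over all covered positions, which began at 306 to 308 and ended at 541. The share depends on that length and is not the share of RNA molecules that reach past the end. KO exceeded WT by 0.0695 percentage points (exact two-sided permutation p = 0.333). The first base past the end kept 28.7% and 33.9% of the depth at the mature end in WT, and 32.6% and 31.6% in KO, with no separation of the groups. The second base kept 10.4% and 8.73% in WT, and 12.1% and 12.2% in KO. At 9 bases the order was turned, with 0.432% and 0.595% in WT and 0.403% and 0.324% in KO. As the first base past the end is an A in the genome, a templated A and an A added after transcription are not told apart by depth.

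**Figure D2:**
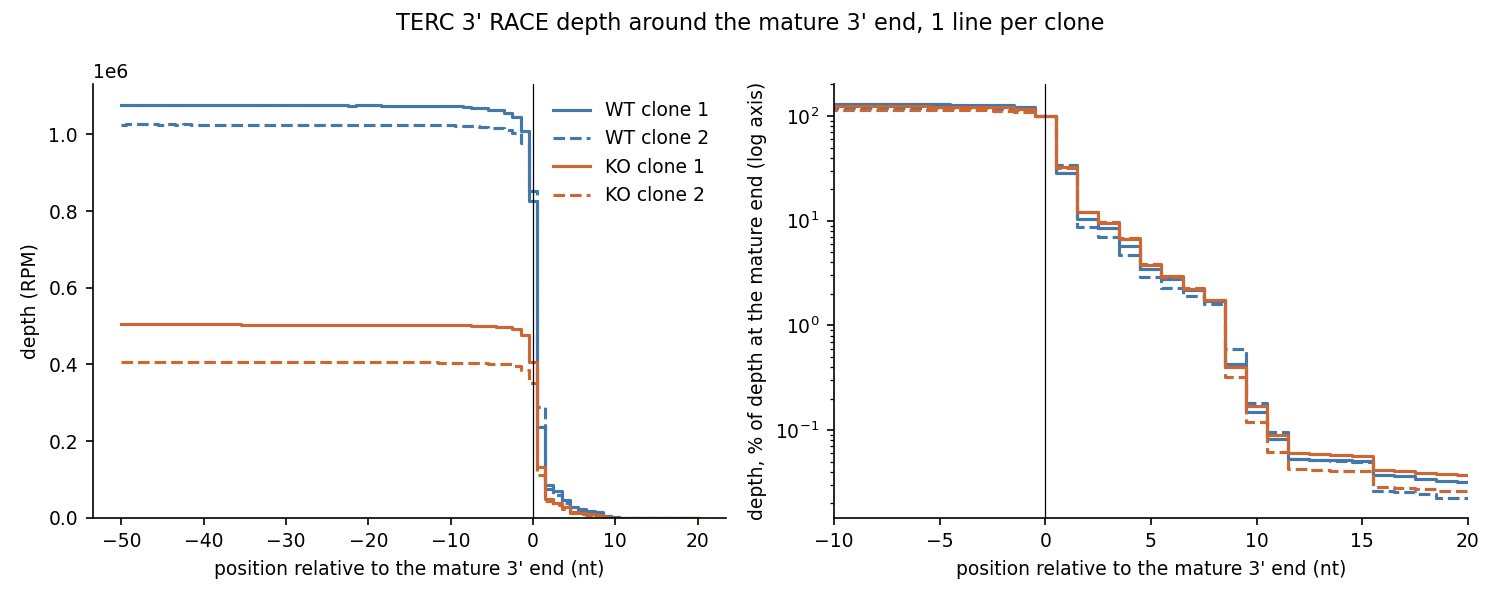
RACE depth in RPM from 50 bases before to 20 bases after the mature TERC 3' end (left), and depth as a percentage of the depth at the mature end on a log axis (right), with 1 line per clone (WT blue, KO orange). Both KO clones lie below both WT clones in the deposited RPM, whose total is unknown, at peaks of 504532 and 406294 against 1077106 and 1025977, and the scaled profiles fall over the same bases.

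Across the transcriptome, 2603 of 17609 tested genes changed, 1201 higher and 1402 lower in KO (edgeR adjusted p below 0.05). A log2 fold change beyond 1 was seen for 584 of the changed genes, 388 higher and 196 lower. Genes with a count numbered 20043, 19736 and 19663 in WT replicates 1 to 3. In KO replicates 1 to 3 they numbered 20753, 20856 and 21141. Whether this difference in detection bears on the excess of large rises was not tested. Of 13540 protein-coding genes tested, 2407 changed.

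Of the 12 largest rises, 3 were of genes with at most 3 counts in WT. MASP1, a serine protease of the lectin complement pathway, had 0 counts in the WT and 1017 in the KO libraries, at least 331-fold higher against a floor of 3 counts over the group. PRMT8, an arginine methyltransferase of the brain, had 0 and 506 counts, at least 165-fold higher. NLRP2 had 1 count in WT and 287 in KO, a ratio of 280 (exact 95% Poisson interval 49.9 to 11098). Such floors and intervals, here and below, allow for counting error alone, which the spread between replicates exceeded, so they are too narrow. INHBE, which encodes the inhibin beta E chain, went from 1.76 ± 1.31 to 37.4 ± 1.04 CPM, B4GALNT2 from 0.326 ± 0.0486 to 5.37 ± 0.717 CPM, and HTR7, a serotonin receptor, from 0.464 ± 0.0800 to 7.33 ± 1.06 CPM (SD, n = 3; edgeR adjusted p of 0.000175, 3.05e-07 and 2.01e-08). The other large rises were those of ARHGAP9, ARSL, TBX15, PHYHD1, CTCFL and BEST1, with log2 fold changes from 4.11 to 4.83. Without WT replicate 3 the values were 7.32 for CTCFL, 6.18 for ARSL and 5.30 for BEST1, without WT replicate 2 they were 5.83 for ARHGAP9 and 5.11 for INHBE, and without WT replicate 1 they were 7.21 for TBX15 and 4.24 for ARHGAP9. Without KO replicate 1, TBX15 was at 3.59. The 1 WT count of NLRP2 came from replicate 3. CTCFL lost its call without KO replicate 1 (adjusted p = 0.0634), without a filter (0.0856) and with a filter of 1 CPM (0.0757). TBX15 lost it without KO replicate 1 (adjusted p = 0.145) and with limma-voom (0.0753). BEST1 lies over FTH1, and ARHGAP9 over GLI1 and MARS, on opposite strands, so some of their reads may belong to these neighbours.

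Of the largest falls, 4 had no count in KO. COL11A1, a chain of fibrillar collagen, had 898 counts in WT and was at least 307-fold lower in KO. TCEAL9 was at least 163-fold lower, FZD10, a Wnt receptor, at least 140-fold lower, and FZD10-AS1, its divergent neighbour, at least 120-fold lower. FBXO17 had 1201 counts in WT and 1 in KO (ratio 1231, exact 95% Poisson interval 221 to 48662). SLC16A14 had 1404 and 2 (ratio 720, interval 199 to 5947), and COL24A1 had 336 and 1 (ratio 344, interval 61.4 to 13643). CALHM2, BNC1, TRPC4, GABRA5 and CAPN6 had log2 fold changes between −5.65 and −4.14, and TRPC4 was not called by DESeq2 (adjusted p = 0.0545). CALHM2 was at −5.06 without KO replicate 1 and −6.63 without KO replicate 3, and TRPC4 had its 10 KO counts in KO replicate 3 alone. The KO counts of FBXO17, SLC16A14 and COL24A1 were all in KO replicate 1. GABRA5, a GABA receptor subunit, fell from 19.2 ± 5.17 to 0.667 ± 0.361 CPM, and CAPN6 from 29.1 ± 0.282 to 1.64 ± 1.00 CPM (SD, n = 3; edgeR adjusted p of 2.99e-11 and 6.47e-11).

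Genes of the ATF4 and unfolded protein response list rose together in KO. Of 25 tested genes in the list for ATF4, the transcription factor of the integrated stress response, and the unfolded protein response, 22 rose and 1 fell, with the same counts adjusted over the list alone. The median log2 fold change was 1.15 (camera adjusted p = 4.18e-140; adjusted p = 0.000799 with an estimated correlation). CHAC1, which degrades glutathione, rose from 20.7 ± 2.33 to 289 ± 3.41 CPM (log2 fold change 3.80, SE 0.08, edgeR adjusted p = 1.24e-20). PSAT1 of serine synthesis rose by 1.92, PCK2, the mitochondrial PEP carboxykinase, by 1.68, and SLC7A5, a carrier of large neutral amino acids, by 1.52 on the log2 scale (adjusted p of 3.15e-17, 7.71e-16 and 7.71e-16). HSPA5, the endoplasmic reticulum chaperone, was the gene that fell (−0.25, adjusted p = 0.0108), while ATF5 (0.23) and DNAJB9 (−0.43) were not past the threshold; these 3 are named after their values were seen.

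Genes of cholesterol synthesis fell in KO. Of 23 tested, 15 fell and none rose, 18 fell when adjusted over the list alone, and the median log2 fold change was −0.40 (camera adjusted p = 1.42e-14; adjusted p = 0.0116 with an estimated correlation). INSIG1, a sterol sensor, fell from 212 ± 12.3 to 105 ± 2.56 CPM (log2 fold change −1.01, SE 0.06, edgeR adjusted p = 1.52e-11). MSMO1 had a log2 fold change of −1.38 and FDFT1 of −0.57, both enzymes of the pathway (adjusted p of 6.74e-10 and 6.02e-08).

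The p53 target list shifted up in camera (8 of 23 rose and none fell, 9 adjusted over the list alone; median 0.34, camera adjusted p = 4.14e-09), with adjusted p = 0.082 with an estimated correlation. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose to 58.6 ± 0.304 CPM in KO (SD, n = 3; log2 fold change 1.55, SE 0.11, edgeR adjusted p = 9.32e-11). SESN2 (1.86), which is in the ATF4 list too, BTG2 (0.60) and AEN (0.56) also rose, with adjusted p of 1.7e-15, 3.93e-08 and 2.72e-07. Without SESN2, 7 of 22 rose, in a test that was not in the fixed design. The unadjusted camera p was then 4.71e-06, against 4.78e-10 for the whole list, and 0.0303 with an estimated correlation. BAX was at −0.04 and TNFRSF10B at 0.05 (adjusted p of 0.862 and 0.829), both named after their values were seen.

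The remaining lists with a camera call were weaker. Of 35 clustered protocadherins, 4 rose (camera adjusted p = 0.0285; adjusted p = 0.242 with an estimated correlation), and the count was the same adjusted over the list alone. They were PCDHB5 (1.16), PCDHB2 (1.93), PCDHB3 (1.74) and PCDHGC3 (0.80), which share sequence or exons with the other members, so their counts are uncertain. Of 17 neural lineage markers, 5 rose and 2 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.0495; adjusted p = 0.256 with an estimated correlation). The median log2 fold change of the neural list was 0.06. MAP2, a neuronal microtubule protein, rose from 16.4 ± 3.34 to 76.6 ± 3.18 CPM (edgeR adjusted p = 1.83e-12), and PAX6 (1.44), NEUROG2 (0.97) and SOX2 (0.29) rose too. The 2 that fell were OLIG2 (−0.56) and POU3F2 (−0.70), with edgeR adjusted p of 0.00103 and 0.0498, named after their values were seen. Leaving out WT replicate 1, KO replicate 2 or KO replicate 3 ended the call of the neural list, with adjusted p of 0.0827, 0.0577 and 0.0948. Fry called these and the preceding 3 lists in the same directions (adjusted p from 2.1e-05 to 0.00722).

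**Figure D3:**
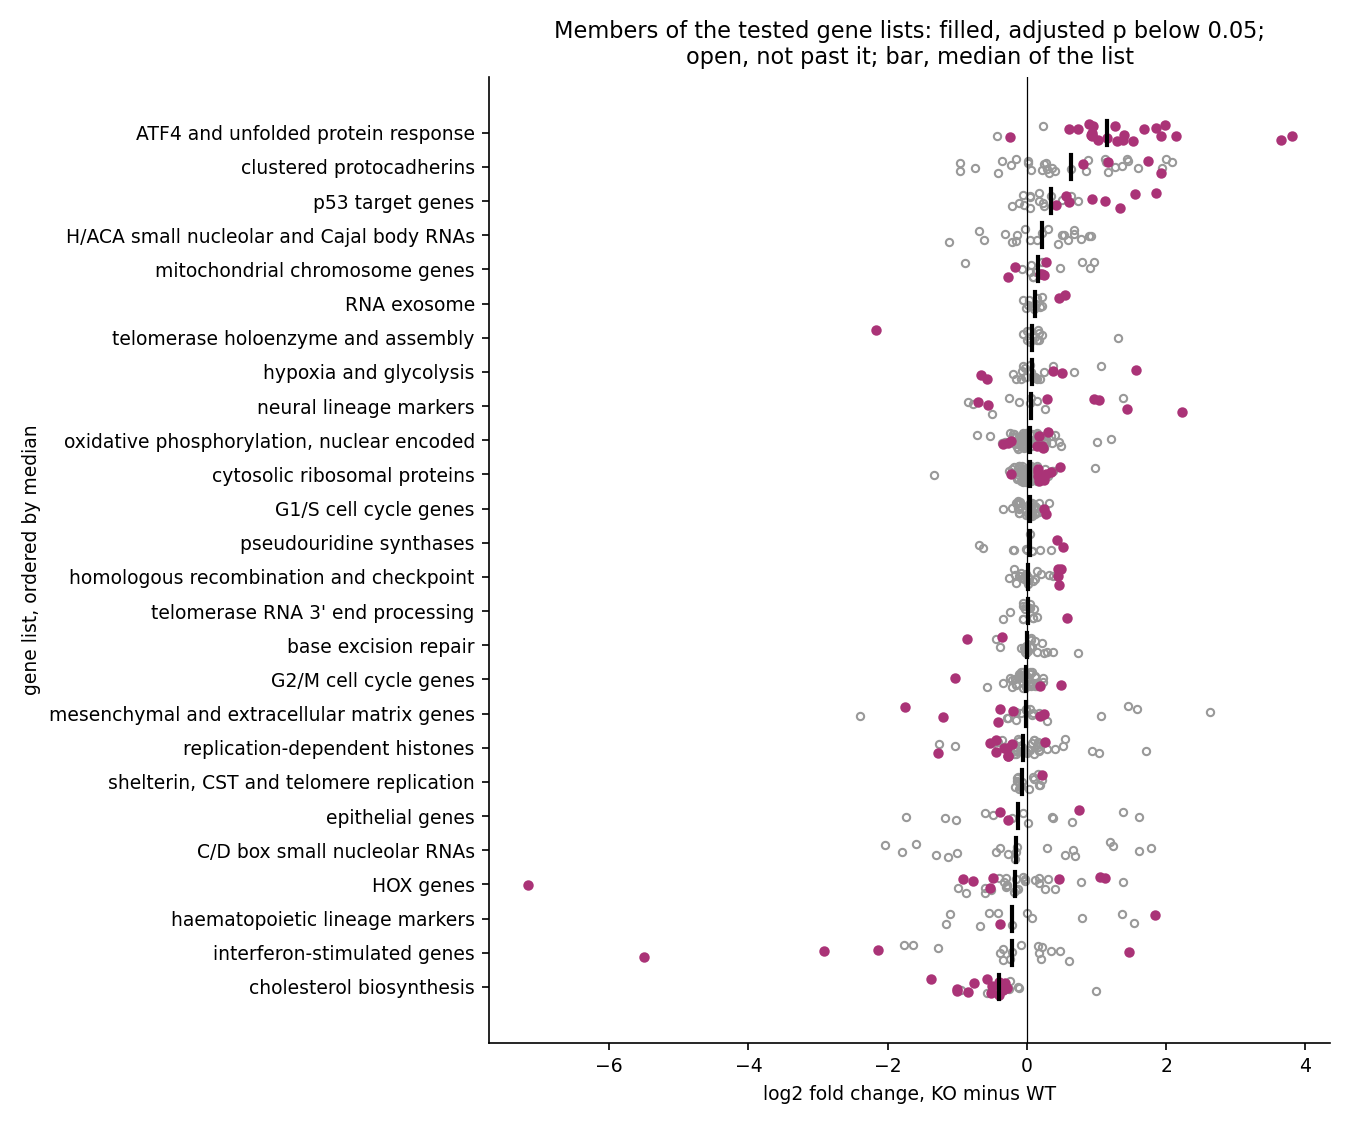
Log2 fold changes (horizontal axis, KO minus WT) of the members of the 26 tested gene lists (vertical axis, ordered by median); filled points have an edgeR adjusted p below 0.05, open points do not, and the bar is the median of the list. The ATF4 list has the highest median, 1.15, and the cholesterol list the lowest, −0.40.

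In base excision repair, 0 of 24 rose and 2 fell, PARP2 (−0.36) and NEIL2 (−0.86), and 0 adjusted over the list alone. UNG (0.05) and TDG (0.29), the other uracil glycosylases named beforehand, had adjusted p of 0.919 and 0.39. In homologous recombination and checkpoint, 4 of 24 rose (4 adjusted over the list alone), namely NBN (0.45), ATM (0.46), MRE11 (0.49) and BRCA2 (0.44), and in the shelterin and telomere replication list 1 of 17 rose, TNKS (0.22), and 0 adjusted over the list alone. Of 14 exosome genes, EXOSC5 (0.46) and EXOSC8 (0.54) rose, and of 13 pseudouridine synthases, PUS1 (0.52) and TRUB1 (0.43) rose, with 2 and 3 adjusted over the list alone. No H/ACA RNA (of 21) and no C/D box RNA (of 20) changed in edgeR; none had an unadjusted p below 0.05, and limma-voom and DESeq2 called 0 in either list. Their median log2 fold changes were 0.21 and −0.16. The camera adjusted p values of these 7 lists ran from 0.294 to 0.982, while fry called the recombination and checkpoint list (adjusted p = 0.0215) and the exosome list (adjusted p = 0.0333) higher. Each of the 11 changed genes of this paragraph lost its call in at least 1 of the 6 fits that left out a library, with adjusted p then between 0.0509 and 0.403. NEIL2 was not called by limma-voom (adjusted p = 0.0916) or DESeq2 (adjusted p = 0.0535) either.

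Lineage, growth and signalling lists moved both ways. Of 20 interferon-stimulated genes, OAS2 (1.47) rose and BST2 (−2.91), IFIT1 (−2.14) and IFIH1 fell, IFIH1 with 103 counts in WT and 2 in KO. Of 13 haematopoietic markers, TAL1 (1.84) rose and GATA2 (−0.38) fell, and of 34 HOX genes, 3 rose and 5 fell, with HOXB9 at 1.12, HOXD13 at 1.05 and HOXA13 at 0.46, and with HOXC11 at 196 counts in WT and 1 in KO. In the mesenchymal list, 2 of 24 rose and 5 fell, with CCN1 at −1.20, THBS1 at −1.75, ZEB1 at −0.38 and VIM at −0.20. In the epithelial list, 1 of 16 rose, KRT8 (0.75), and 2 fell, JUP (−0.38) and DSP (−0.27). Of 25 hypoxia and glycolysis genes, 3 rose and 2 fell, with VEGFA at 1.56, BNIP3 at 0.51, PDK1 at 0.38 and ENO2 at −0.66. Adjusted over the list alone, the numbers that rose and fell were 1 and 3 for interferon, 1 and 1 for haematopoietic, 3 and 6 for HOX, 4 and 5 for mesenchymal, 3 and 2 for epithelial, and 8 and 2 for hypoxia. The calls of IFIT1, IFIH1, VIM, DSP and PDK1 were each lost in at least 1 fit without a library (adjusted p between 0.051 and 0.27), and that of IFIH1 with limma-voom too (adjusted p = 0.0709). IFIT1 was at −2.78 without KO replicate 1, the 2 KO counts of IFIH1 were in KO replicate 2, and the 1 KO count of HOXC11 was in KO replicate 1. The hypoxia list as a whole was past the camera threshold without WT replicate 1 or 2 (adjusted p of 0.0392 and 0.0376).

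In the cell cycle lists, MCM5 (0.28) and CDCA7 (0.25) rose of 36 G1/S genes, and HMMR (0.49) and CDC20 (0.19) rose and NDC80 (−1.03) fell of 39 G2/M genes, with the same counts adjusted over the list alone. Of 48 replication-dependent histones, 1 rose and 9 fell (2 and 10 adjusted over the list alone), with H2BC15 at −1.27, H4C12 at −0.53, H2BC17 at −0.28 and H2BC7 at −0.27. Of 81 nuclear genes of oxidative phosphorylation, 5 rose and 3 fell (3 and 2 adjusted over the list alone), with ATP5PB at 0.30, CYC1 at 0.18, NDUFB10 at −0.34 and ATP5MC2 at −0.23. Of 18 genes of the mitochondrial chromosome, 4 rose and 2 fell (6 and 2 adjusted over the list alone), with MT-ND5 at 0.27, MT-CO1 at 0.22, MT-CO2 at 0.19 and MT-ATP8 at −0.27. Of 82 cytosolic ribosomal proteins, 8 rose and 1 fell (4 and 1 adjusted over the list alone), with RPS12 at 0.47, RPL30 at 0.35, RPLP2 at 0.28 and RPL10 at −0.23, and pseudogene copies make these counts uncertain. Of the cancer testis antigens, MAGEC3 was the one tested, and it rose from 0 counts in WT to 114 in KO, at least 37.1-fold. The other tested member of that list, SSX2IP (0.47, edgeR adjusted p = 0.0694), matched by its name and is a centrosomal protein, not such an antigen. None of the lists of this and the preceding paragraph with at least 5 members was past the camera threshold (adjusted p from 0.0547 to 0.944). Fry called the hypoxia list higher (adjusted p = 0.00722), and the mesenchymal (0.0215), interferon (0.0377) and HOX lists (0.0439) lower. The test and the median or mean took opposite signs for the telomerase, shelterin, mesenchymal, epithelial and haematopoietic lists, none of them called by camera. The calls of CDC20, CYC1, NDUFB10, MT-CO2, MT-ATP8, RPL30 and MAGEC3 were each lost in at least 1 fit without a library (adjusted p between 0.0501 and 0.146), and that of MT-ATP8 with DESeq2 too (adjusted p = 0.191). As whole lists, the mitochondrial chromosome passed the camera threshold without WT replicate 1 (adjusted p = 0.00278), the ribosomal proteins without KO replicate 1 (adjusted p = 0.0344) and the histones without WT replicate 3 (adjusted p = 0.047).

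No chromosome shifted as a whole. Camera called 0 of 23 chromosomes, with 0 at an unadjusted p below 0.05, and adjusted p values of 0.902 and 0.928. Fry, which does not compare a chromosome with the others, called 5. The chromosome medians lay between −0.04 on chromosome 22 and 0.07 on chromosome 18. On chromosome 3, which carries TERC, 67 of 991 tested genes rose and 47 fell, and on chromosome 19, 61 of 1205 rose and 148 fell.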

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

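The count of 2603 changed genes stayed within 1.5 times under every alternative: 2611 with DESeq2 size factors, 2629 with library totals, 2718 without a filter, 2800 with 1 CPM in 3 libraries, 2682 with limma-voom, 2863 with the DESeq2 Wald test, and 1923 to 2279 without 1 library. In a single simulated draw of this comparison (17348 genes tested), 16.7% of the DESeq2 calls were false, against 1.68% with edgeR. Its dispersions came from edgeR, which can favour edgeR. A far smaller share of genes was changed in it than was called here, which can raise the false share of calls. These shares are thus no error rates of the real calls. TERC stayed past the threshold with −2.25 to −2.10, and SMUG1 short of it with 0.16 to 0.34. Of 26 lists, 5 were called at the preset correlation and 2 with an estimated inter-gene correlation, the ATF4 and cholesterol lists, while adjusted p rose to 0.082 for p53 targets, 0.256 for neural markers and 0.242 for protocadherins. The hypoxia list was called with DESeq2 size factors (adjusted p = 0.0476) and with the replicate block (0.0484), and the neural list was not without a filter (0.087). Without 1 library, 4 to 6 lists were called, and adjusted p ran from 0.0376 to 0.142 for hypoxia, 0.0233 to 0.0948 for neural markers, 0.00278 to 0.793 for the mitochondrial chromosome, 0.0344 to 0.804 for ribosomal proteins and 0.047 to 0.329 for histones. Of 100 named genes past the threshold, 74 stayed past it in every alternative, 25 lost it in at least 1 fit with a library left out, where fewer samples were tested, and 8 in another alternative. Genes with almost no change turned sign: NOP10 was at −0.01 with limma-voom, and without 1 library the ranges were −0.02 to 0.28 for TERT, −0.07 to 0.13 for DKC1, −0.08 to 0.13 for NOP10, −0.14 to 0.02 for TENT4B, −0.16 to 0.19 for TOE1 and −0.12 to 0.15 for UNG. The replicate numbers did not pair the RNA-seq libraries: same-numbered libraries deviated together with correlations of −0.011, 0.004 and 0, and not every library correlated best with its own number. With the replicate number as a block, 2668 genes were called, and among the named genes NEIL2, TRUB1, MRE11 and IFIH1 were not. The RACE clones are separate clones that share only a number, and no block was fitted to them. The KO mean of the RACE share past the mature end stayed above the WT mean, by 0.0555 to 0.0835 percentage points without 1 clone, by 0.172 with positions from 400 on as denominator, by 0.0372 to 0.0975 with the boundary moved by up to 2 bases, and by 1.71 with the maximum, where WT clone 2 (28.2%) lay above both KO clones (26.3% and 27.4%). Alternatives for normalized values had nothing to act on.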

Other observations

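Of the tests below, that of the trend over gene length, GC content and expression level was set down before its result was seen. Those on the H/ACA RNAs, the genes around TERC, the shared reads, the scaling, the neighbours of genes seen in 1 group and the other splits were chosen after the result was seen. The neighbour rule was also changed after a first result: neighbours that were themselves seen in 1 group had been left out, and were then counted. The genes named next were singled out after their values were seen. Within the ATF4 list, several genes of amino acid supply rose: SLC7A11, the cystine carrier, had a log2 fold change of 2.14 (SE 0.12, edgeR adjusted p = 2.89e-12), ASNS, the asparagine synthetase, 1.98 (adjusted p = 1.95e-15), and CTH of cysteine synthesis 1.38 (adjusted p = 2.89e-13). DDIT4, an inhibitor of mTORC1, was at 3.65 and TRIB3 at 1.30 (adjusted p of 1.93e-07 and 1.14e-10). ATF4 itself was at 0.95 and XBP1 at 0.94 (adjusted p = 2.97e-12 for both). In the endoplasmic reticulum, HERPUD1 of protein degradation rose by 1.39 and the chaperone HSPA5 fell by 0.25 on the log2 scale (adjusted p of 1.14e-11 and 0.0108). In the cholesterol list, HMGCS1 fell from 22.3 to 11.2 CPM (adjusted p = 0.000194).

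Counts almost only in 1 group were seen for 23 changed genes, with at most 3 counts over one group and a mean of at least 1 CPM in the other. Of these, 9 were seen in WT, on 5 chromosomes, and 14 in KO, on 10 chromosomes. Those seen in KO include CA12, a carbonic anhydrase (0 and 139 counts), NUTM1, a testis gene (1 and 170 counts), NLRP12 (0 and 172 counts) and CLDN19 (0 and 133 counts). Those seen in WT include HOXC11 and the neighbours TCEAL8 and TCEAL9 on chromosome X (127 and 476 counts in WT, 0 in KO). Between replicates, counts varied far beyond counting error at every level, with a variance of 10.9 to 16.5 times the mean between averages of 3 and 3000 counts. A ratio that high at the lowest counts would arise if several reads came from 1 molecule, which was not tested. Whatever its source, this spread weakens the floors and intervals given for genes with few or no counts in a group.

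For the lower TERC count in KO, a lower yield of short structured RNAs would pull H/ACA RNAs down with TERC. Their median log2 fold change was 0.21 (bootstrap 95% interval −0.14 to 0.53, 21 genes), above −1. Of 241 H/ACA entries, only these 21 passed the filter. The interval resamples genes and leaves out the error of each gene's own value. Some H/ACA RNAs lie inside host genes, such as DKC1, and whether host reads entered their counts was not tested. The tested entries thus showed no common fall, but a lower yield of TERC is not excluded. A lost DNA segment over most genes within 2 Mb of TERC would lower their median by at least 1 on the log2 scale. The median of 25 tested genes there was 0.29 (bootstrap 95% interval −0.17 to 0.51). It does not show a loss that reaches only a few of these genes. Of the nearest tested genes on either side, MECOM (0.43) was called higher, and ACTRT3 (0.25, edgeR adjusted p = 0.939) had no clear direction. LRRC31 (2.58) was called higher, and CLDN11 (−3.98) and RPL22L1 (−1.12) further off were called lower. A loss of TERC from all KO cells would leave no counts, and the 408, 394 and 464 counts in KO replicates 1 to 3 argue against it. A loss of TERC from only part of the cells is not excluded. How reads were credited stays open: of genes inside a same-strand exon 3.64% have any count, which does not show whether the outer gene keeps the shared reads, so a shift of reads within the locus cannot be told apart from a lower amount of RNA. Genotype and clone also stay open, as the RNA-seq libraries of each genotype carry 1 clone name.

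Scaling and a trend over genes were tested against the rise of the ATF4 list, and neither accounts for it. A scaling factor shifts every gene alike, and the median log2 fold change of the list exceeded that of all other tested genes by 1.14 (bootstrap 95% interval 0.92 to 1.51, 25 genes). With the trend over transcript length, GC content and expression level taken off, the median was 1.16 (bootstrap 95% interval 0.92 to 1.53, 25 genes). A candidate explanation left open is the state of the cultures at harvest, such as amino acid supply, which the design does not part from genotype or clone. As a hypothesis, the KO line may carry a lasting stress response, which would need cultures of further clones fed alike.

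Genes seen in 1 group only may have been lost with a DNA segment or silenced. Neighbours were the nearest tested genes on either side that did not overlap the gene and had at least 1 CPM on average in WT or KO. Those of the 9 genes seen in WT lay 0.2 to 1320.3 kb away. Their median log2 fold change was −0.26 (bootstrap 95% interval −1.28 to −0.1, 18 neighbours), and 5 of 18 were at −1 or lower. Most of these were each other's neighbours, FZD10 with FZD10-AS1 and TCEAL8 with TCEAL9, so their low values follow from how they were chosen. The remaining one was OLFM3 (−1.65), 879.4 kb from COL11A1. Loss of a segment and silencing cannot be told apart here, since the neighbours are few and a loss can end before them. None of the 28 neighbours of the genes seen in KO was at 1 or higher.

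With 3 libraries against 3, the number of splits is too small to reach a share under 0.05. The real split gave 2603 changed genes, 1 of the 10 splits, and the highest of the others gave 0, where edgeR found 284 to 400 genes with an unadjusted p below 0.05. Every other split mixes WT and KO in both groups, so a difference between WT and KO widens the spread within them. Their 0 calls are therefore no measure of what chance alone gives.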
